A study of Mus musculus with 2 samples.

How the data were processed

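The data were 1 LHX6 ChIP-seq library and 1 input library from pooled maxillary arches of mouse embryos at E11.5, with 20 µg of chromatin used for the immunoprecipitation per the labels' protocols. Reads were aligned to mm9 with BWA and extended to 150 bp fragments whose density along the genome was recorded, per the labels' protocols. MACS is named per the submitters' processing notes, with no version. The settings and threshold of the interval calling, and the read totals, are not given in the sources used here. The labels' protocols also describe an H3K27ac experiment, which was not analysed here.

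The deposited table lists intervals of both libraries with a signal for each: the highest fragment density (height) and the mean density over 32 bp bins, as the authors' values. It has no fold enrichment and no p-value. The mean density times the number of bins was whole within 0.02 for 99.97% of the 6572 intervals, and summits lay inside their intervals in 100%. Whether the density was scaled between the libraries is not stated, so the ratio of LHX6 to input height may include a difference of depth. The table also gives CpG islands and, for each interval, the genes nearby with their distance from the gene start, as annotated by the authors; 1544 intervals were assigned to 2 or more genes, so an assigned gene is not always the nearest. No column of other samples was present, and no interval lay on random sequences or the mitochondrial genome.

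The build was checked against NCBIM37 with GENCODE M1 genes: of 5405 distances for genes matched by a unique name, 27.8% equalled the deposited distance and 75.1% lay within 200 bp of it, and no interval passed the end of a chromosome. Older gene names were matched to current symbols through a RefSeq gene table of GRCm38.p6, used for names alone; of 5258 symbols, 4731 (90%) were found in GENCODE M1. Random positions for comparison were 100000 draws, of which 96966 were not N.

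The groups, the tests, the named genes, the 16 gene lists and the alternatives were fixed before the data were examined, except those named as chosen later. Named genes were all LIM homeodomain and cell cycle list members with an interval, genes of the 10 highest intervals, up to 4 members with the highest intervals from each other list, and the 5 genes with most intervals; 2 genes that this rule takes are not reported here. Genes named only as the nearest to an intergenic interval, the members of other lists with no interval and the genes of the input intervals were named after their values were seen. Gene lists were compared with all 33797 GENCODE symbols by two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists, and with protein-coding genes as an alternative, since the full set holds small RNAs and pseudogenes. Matched lists were random genes drawn within groups of similar length, or from protein-coding genes within groups of similar length and CpG content. Heights were compared by permutation tests of medians with 100000 resamples, and distances between intervals with 1000 random placements.

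For motifs, 200 bp windows at the centre of an interval were compared with windows 2 kb to the left and to the right. Because each centre has 2 flanks, the exact sign test was conditioned on the number of windows of an interval with the motif, so that with no effect the centre holds it in 1 of 3 cases when 1 window has it. The test was first run against an even split, which is wrong for 2 flanks and gave a p for TAATTA over all intervals in the direction opposite to its percentages; it was replaced after that result had been seen. Sign tests against 1 flank at a time are given as alternatives. The middle of the interval was the centre for TAATTA over all intervals and, where no summit is named, in distal intervals and at gene starts; the summit was the centre for all other motif results. The hexamer scan, run on 3 sets of intervals, the octamers, the A and T palindromes, the matched hexamers and the spacing of 6 pairs of hexamers over 760 spacings were chosen after the data were seen. Spacings from 1 to 40 bp were counted in intervals within 400 bp windows and tested against the mean of all spacings of the pair with a one-sided exact Poisson test. They had first been counted in pairs of sites over 3 pairs of hexamers, and the count in intervals and the other 3 pairs were chosen after that result was seen. Hexamers of the same composition were used to compare motifs between base compositions, with 95% intervals from 1000 bootstrap draws, as for gene starts with and without an interval. TAATTA reads the same on both strands and some of its matched hexamers do not, which gives those more chances to occur. The interval of the ratio of TGATTG shares between facial mesenchyme factors and other distal intervals is from a normal approximation on the log scale, and that of the ratio to random positions from the share alone. Intervals of the X ratios are exact Poisson intervals.

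The tests were tested on simulated data. On random genome windows 3.99% of 2080 hexamers had a p under 0.05 and 0 passed after adjustment, and a hexamer planted in 10% of the windows ranked 1. These windows had no difference in base composition between centre and flanks, so this does not cover such a difference in the data. There 747 hexamers were enriched and 1121 depleted at gene starts, and 799 and 686 in distal intervals. A spacing of 4 bp planted in 12 windows was found as the leading spacing, and 0 spacings passed without it. Random gene lists had a p under 0.05 in 3.56% of 1600 tests, and planted lists were found in 100 of 100 runs. The median test had a p under 0.05 in 0% of 200 shuffles of these whole-number heights, with many ties, and found a shift of 2 in 50 of 50 runs. The clustering test had a p under 0.05 in 6% of 200 random placements. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9 were used.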

Results

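Binding of LHX6, a LIM homeodomain transcription factor expressed in the mesenchyme of the first pharyngeal arch, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in the maxillary arch, the embryonic tissue that forms the upper jaw and the palate. Tissue from 47 wild-type CD-1 mouse embryos at E11.5, midway through gestation, was combined, and the data comprised 1 LHX6 ChIP library and 1 input library of chromatin without antibody. The series title states that the aim was to find a cis-regulatory element that LHX factors act on. There were no replicates in either group, so no value below carries a replicate error. The read totals of both libraries are unknown here, so depth could not be compared between them. Intervals are regions of enriched fragment density, and the height of an interval is the highest density of 150 bp fragments within it, as given by the authors. Confidence intervals of shares are exact Clopper-Pearson 95% intervals, all intervals cover counting error only, and tests across intervals or genes describe this 1 library. Coordinates are those of mouse build NCBIM37 (mm9).

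LHX6-enriched chromatin was found at 6566 intervals, which together covered 6.28 Mb or 0.238% of chromosomes 1 to 19 and X. The median interval was 857 bp long with a height of 22 (interquartile range 18 to 28), and 306 intervals reached a height of 50. Among the 10 highest intervals were 1 in an intron of Wnt11, a secreted WNT ligand (chromosome 7, 105991892 to 105992852, height 131), 1 in an intron of Dpyd, which encodes a pyrimidine-degrading enzyme (chromosome 3, 118348613 to 118349961, height 126), and 1 within 1 kb of a GENCODE transcript start of Myst4, which encodes a histone acetyltransferase and is now called Kat6b (chromosome 14, 22318949 to 22320595, height 126). An interval of height 120 lay in an intron of D6Mm5e (chromosome 6, 82937081 to 82938036). An interval of height 147 lay at the start of Mpnd (chromosome 17, 56146953 to 56149242) and was also assigned to Sh3gl1 and AW049765. Of the intergenic intervals in this group, 1 lay 15.1 kb from Frzb, a secreted WNT antagonist (chromosome 2, 80236234 to 80238060, height 137), and 1 lay 87.2 kb from Postn, which encodes the matrix protein periostin (chromosome 3, 54281767 to 54282586, height 127).

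The 3 highest intervals were also enriched in the input library. They lay at Mirn715 and LOC627695 (chromosome 17, 39979824 to 39985891, height 297), in an intergenic region 61.1 kb from Axin2 (chromosome 11, 108872537 to 108873657, height 177) and in an intergenic region 284 kb from Pxmp3 (chromosome 3, 5860216 to 5860975, height 151). The input library had 6 intervals in all, and each overlapped an LHX6 interval. At the 3 highest the start and end were identical in both libraries, so this overlap need not come from separate calls. The other 3 were assigned to Camk1d, Cdk8 and Mid1. The LHX6 height was 1.54 to 3.08 times the input height, and it was under 2 times at 3 of the 6, with a Spearman correlation of 0.943 across these 6 intervals. The deposited list gives input values for no other interval.

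LHX6 intervals were concentrated at gene starts. Of the 6566 intervals, 2354 (35.9%, 34.7 to 37.0) had their summit, the position of the highest density, within 1 kb of an annotated gene start, and 92.5% of these overlapped a CpG island. The other 4212 intervals, called distal here, comprised 1666 inside genes, 313 upstream and 244 downstream of genes, and 1989 (30.3%, 29.2 to 31.4) with no annotated gene; 13.1% of them overlapped a CpG island. With GENCODE transcripts, 38.9% of summits lay within 1 kb of a protein-coding start, against 2.36% of random positions, a ratio of 16.5 (16 to 17). Introns held 22.5% of summits against 34.6% of random positions, and intergenic sequence over 10 kb from a gene held 29.8% against 51.0%.

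Intervals at gene starts were lower than distal intervals, with a median height of 21 against 23 (difference of medians -2, two-sided permutation test, p = 2e-05). When the intervals were ranked by height in 10 equal groups, gene starts made up 15.2% (12.6 to 18.2) of the highest group and 32.6% to 44.1% of each of the others. Intervals at gene starts were also longer, with a median of 1016 bp against 799 bp, and their median mean density, the average over the whole interval, was higher by 0.379 (permutation p = 1e-05, the smallest that the resamples can give). The direction thus depended on which measure of strength was used.

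Genes for transcription factors of the facial mesenchyme, the connective tissue of the developing face, had an LHX6 interval in 51 of 64 cases (79.7%, 67.8 to 88.7). This compared with 13.9% of all other genes (odds ratio 24.4, two-sided Fisher's exact test, adjusted p = 7.02e-31 over 16 lists) and with 20.5% of other protein-coding genes (odds ratio 15.2, adjusted p = 1.18e-22). Among the highest intervals in this list were those downstream of Tbx3 (chromosome 5, 120137002 to 120138406, height 75), in an intron of Eya1 (chromosome 1, 14174654 to 14175706, height 59) and in an intron of Runx2, the master regulator of bone formation (chromosome 17, 44754869 to 44756003, height 53). Tbx3 had 8 intervals. Extracellular matrix and signalling genes of cleft palate had an interval in 19 of 38 cases (50%, Fisher's exact test, adjusted p = 7.39e-07), with the highest in introns of the ephrin receptor gene Ephb2 (chromosome 4, 136335836 to 136336969, height 100), of the chromatin remodeller gene Chd7 (height 48) and of the ephrin gene Efna5 (height 39), and 1 of height 32 at Ephb3. Both lists, like housekeeping genes, passed against protein-coding genes matched on length and on CpG content of the start (permutation test within matched groups, adjusted p = 0.0032, the smallest of the 16 lists, and 0.0171). The former value is also the smallest that the matched draws can give.

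Genes of the WNT and hedgehog pathways also had intervals more often than other genes. WNT genes had an interval in 26 of 57 cases (45.6%, Fisher's exact test, adjusted p = 6.75e-08), led by Wnt11 (height 131), an intron of the WNT co-receptor gene Lrp6 (chromosome 6, 134476633 to 134477506, height 96), the receptor gene Fzd2 (height 70) and an intron of Rspo2, an activator of the pathway (height 61). Hedgehog genes had an interval in 8 of 15 cases (53.3%, Fisher's exact test, adjusted p = 0.001), with the highest in introns of the receptor gene Ptch1 (chromosome 13, 63629497 to 63630424, height 55), of Gli3, a transcription factor of the pathway (height 52), and of the co-receptor gene Boc (height 32), and 1 at the start of the co-receptor gene Gas1 (height 28). Both calls held against protein-coding genes (Fisher's exact test, adjusted p = 0.00012 and 0.0141) and were lost when these were matched on length and CpG content (permutation test, adjusted p = 0.168 and 0.315).

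BMP and TGF-beta genes (13 of 37, 35.1%, adjusted p = 0.00235), FGF genes (9 of 27, 33.3%, adjusted p = 0.0157) and forebrain interneuron genes (7 of 21, 33.3%, adjusted p = 0.0324) passed against all genes and not against protein-coding genes (Fisher's exact test, adjusted p = 0.0807, 0.238 and 0.254). The highest intervals of BMP and TGF-beta genes lay in introns of the TGF-beta co-receptor gene Tgfbr3 (height 66), Bmp6 (height 55) and Tgfbr2 (height 37) and upstream of Id3 (height 31). Those of FGF genes lay in an intron of Etv1 (height 36) and at the starts of Dusp6 (height 32), Etv5 (height 31) and Spry4 (height 24). Those of forebrain interneuron genes lay in introns of Sox6 (height 29) and Satb1 (height 24), and near Gbx2 (height 26) and Maf (height 21). Housekeeping genes, which stand for broadly open chromatin, had an interval in 13 of 20 cases (65%, Fisher's exact test, adjusted p = 9.19e-07), led by Ywhaz (height 47), Actb (height 32), Rpl13a (height 31) and Eef1a1 (height 28), all at gene starts. With intervals at gene starts left out, 10% of housekeeping genes (Fisher's exact test, adjusted p = 0.363) and 65.6% of the facial mesenchyme factors (adjusted p = 2.1e-37) had an interval.

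**Figure D1:**
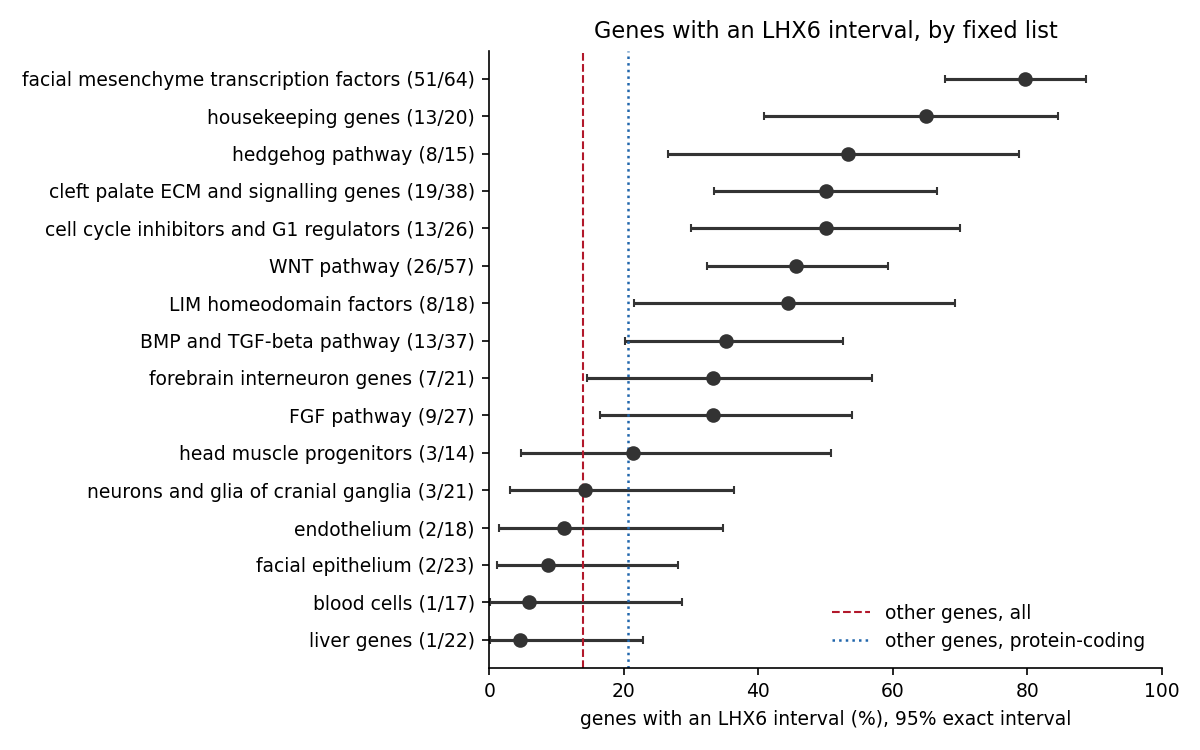
Share of the genes of each fixed list with an assigned LHX6 interval (x axis, percent), with exact 95% intervals as bars and the genes with an interval out of all genes of the list in brackets. The dashed and dotted lines mark all other genes (about 13.9%) and other protein-coding genes (about 20.5%), and facial mesenchyme transcription factors stand highest at 79.7%.

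The lists of facial epithelium, head muscle progenitors, endothelium, blood cells, neurons and glia of cranial ganglia, and liver genes did not pass the test against other genes. Facial epithelium had 2 of 23 genes with an interval (Grhl3, height 34, and Krt8, height 15), head muscle progenitors 3 of 14 (among them Chrna1, height 37, and Pax7, height 14), endothelium 2 of 18 (Fli1, height 44, and Erg, height 19), and neurons and glia of cranial ganglia 3 of 21 (Ntrk2, height 27, Tubb3, height 17, and Neurog1, height 15). Blood cells had 1 of 17 (Nfe2, height 24) and liver genes 1 of 22 (Fgb, height 21); by GENCODE both of these intervals lay within 1 kb of a protein-coding start, 15.2 kb and 5.84 kb from the starts of Nfe2 and Fgb themselves. The adjusted p of these 6 lists ran from 0.511 to 1. The median height of intervals at a list differed from random sets of intervals for 0 of the 16 lists (permutation test, smallest adjusted p = 0.487). With mean density in place of height it differed for 2, being lower at facial mesenchyme factors (9.71 against 10.4) and higher at housekeeping genes (12.5 against 10.4, permutation test, adjusted p = 0.0236 for both).

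LHX6 intervals lay at Lhx6 itself and at Lhx8, its closest relative. LIM homeodomain factors and their cofactors had an interval in 8 of 18 cases (44.4%, Fisher's exact test, adjusted p = 0.00345 against all genes and 0.0454 against protein-coding genes). Lhx6 had 6 intervals, with heights from 13 to 28, the highest 3.46 kb upstream of its start (chromosome 2, 35963964 to 35964927) and another of height 27 at the start (chromosome 2, 35958842 to 35961549). Lhx8 had 5, with heights from 14 to 30, the highest at its start (chromosome 3, 153991789 to 153993929). None of the Lhx6 intervals held TGATTG, TGATTA or TAATTA within 100 bp of the summit. Of the Lhx8 intervals, only that of height 26, 1.77 kb upstream, did, with 1 TGATTG and 1 TGATTA. Ldb2, which encodes a cofactor that binds LIM domains, had 4 intronic intervals with heights of 46, 26, 25 and 18, and Isl2, Ldb1, Lhx1, Lhx2 and Lmo4 had 1 each, with heights from 15 to 22. The call of this list was lost when genes were matched on length (permutation test, adjusted p = 0.127), against protein-coding genes matched on length and CpG content (0.391), and with the higher part of the intervals alone (Fisher's exact test, adjusted p = 0.0807).

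Cdkn1c, which encodes the cell cycle inhibitor p57, had 1 interval at its start (chromosome 7, 150646329 to 150647376). It overlapped a CpG island and had a height of 22, rank 3130 of 6566. Its summit at 150646800 lay in an untranslated exon of Cdkn1c by GENCODE, and 1 TGATTG site at 150646763 to 150646768 on the plus strand, followed by G, lay within 100 bp of it. The nearest intervals downstream were 2 in introns of Kcnq1, a potassium channel gene, 164 kb and 155 kb from the Cdkn1c start. The first overlapped 2 CpG islands and had a height of 33 (150481871 to 150482968), with a TGATTG site at 150482513 to 150482518, also followed by G. The other overlapped no CpG island and had a height of 23 (150491385 to 150492252), with a TGATTA site at 150491723 to 150491728 on the minus strand. Among related genes, Cdkn1b, which encodes the inhibitor p27, had an interval at its start (chromosome 6, 134870001 to 134871407, height 27), while Cdkn1a, Cdkn2a, Cdkn2b, Cdkn2c and Cdkn2d had none in the list.

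**Figure D2:**
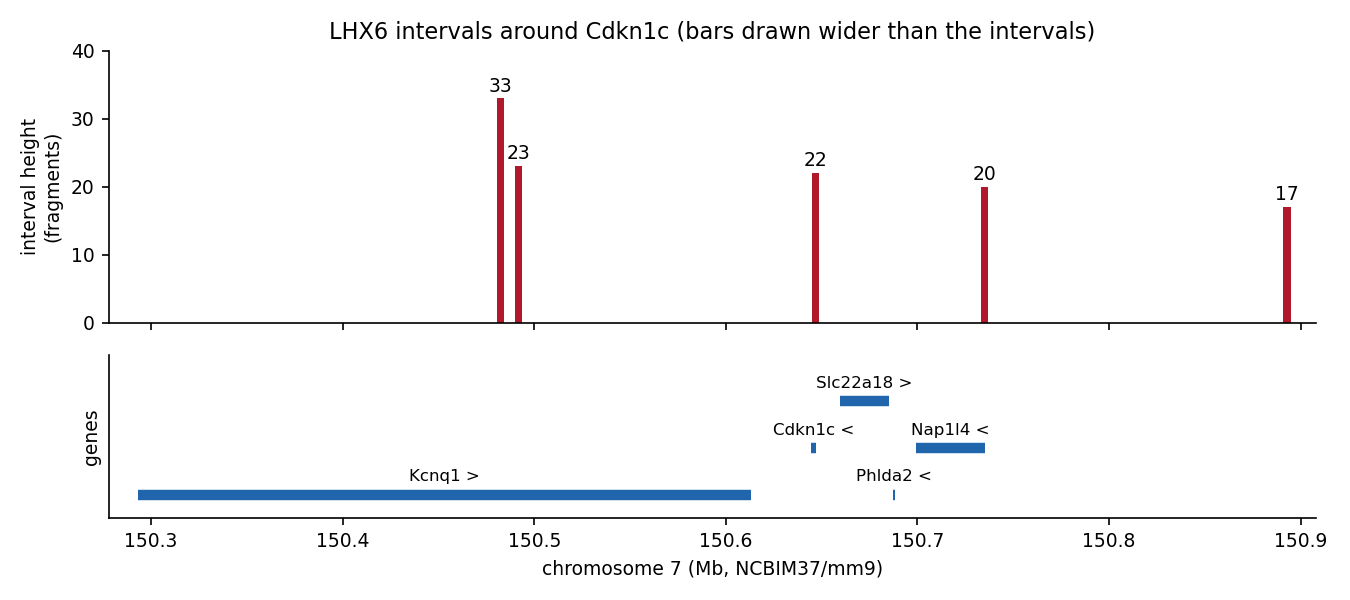
LHX6 intervals (bars, upper panel, height in fragments) and 5 genes of the region (lower panel, arrows give the strand; other genes are not drawn) along chromosome 7 in Mb of NCBIM37. The interval at the Cdkn1c start has a height of 22, and the intronic Kcnq1 intervals have heights of 33 and 23.

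Of all 26 cell cycle inhibitors and G1 regulators, 13 had an interval (50%, Fisher's exact test, adjusted p = 4.31e-05). The highest lay in an intron of E2f3 (chromosome 13, 30005241 to 30005905, height 44), which had a second interval of height 18, and upstream of Ccne1, which encodes cyclin E1 (chromosome 7, 38896743 to 38898004, height 36). Ccnd3 had an intronic interval of height 21 and Ccnd2 an upstream interval of height 16. Intervals of Cdk4 (height 23), Trp53 (19), E2f5 (19), Cdk6 (17) and Rbl1 (15) lay at the gene's own start. Those assigned to Cdk2 (height 23) and E2f4 (height 21) lay 8.71 kb and 8.19 kb from those genes' annotated starts. By GENCODE the intervals of Cdk2 and E2f4 both lay within 1 kb of a protein-coding start, and both overlapped a CpG island. The call held against protein-coding genes (Fisher's exact test, adjusted p = 0.0027). It was lost when these were matched on length and CpG content (permutation test, adjusted p = 0.292) and with distal intervals alone (Fisher's exact test, adjusted p = 0.0679).

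The LIM homeodomain core TAATTA was more frequent at the centres of LHX6 intervals than in their flanks. It occurred in the central 200 bp of 7.55% of intervals against 5.88% of windows 2 kb to either side (exact two-sided sign test, p = 7.59e-06). In distal intervals it occurred at 10.9% of centres against 5.94% of flanks (exact sign test, p = 7.85e-23), and in intervals at gene starts the direction was opposite, with 1.49% against 5.78% (p = 1.89e-19). Against 13 hexamers of the same composition at the summits of gene starts it was not lower, at 1.33 times (0.912 to 1.77) their median and rank 5. Around the summits of distal intervals it occurred in 12.5%, 2.24 times the flanks, the highest ratio to flanks among the 8 palindromic hexamers made of A and T. It was there 1.7 times (1.5 to 1.93) as frequent as the median of the 13 hexamers of the same composition, rank 4. TATATA, of the same composition, occurred at 0.425 times its flank level. With windows of 500 bp around the interval centres the difference over all intervals was not past the threshold (14.9% against 14.1%, exact sign test, p = 0.109). Many hexamers differed between summits and flanks by the same test. Of 2080 hexamers, 813 were enriched and 984 depleted over all intervals, and 799 and 686 in distal intervals. TAATTA ranked 485 at all summits and 40 at distal summits, so a small p alone does not set it apart.

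Hexamers other than TAATTA were more frequent still at distal summits, in a scan of all 2080 hexamers that was chosen after the data were seen. TGATTG occurred within 100 bp of 37.7% (36.2 to 39.2) of distal summits against 8.06% of flanking windows, a ratio of 4.67, and it ranked first by the test of centre against flanks. TGATTA occurred in 33% against 8.83% (exact sign test, p = 7.6e-237). At least 1 of TGATTG, TGATTA and TAATTA was present at 62.8% (61.4 to 64.3) of distal summits and 20.5% of flanks. CATCTG and CAGCTG, which are E-boxes bound by basic helix-loop-helix factors, occurred in 30.1% and 19.3% of distal summits against 15% and 8.30% of flanks (exact sign tests, p = 2.32e-84 and 1e-67). Relative to the median hexamer of the same composition there, CATCTG was 4.83 times (4.42 to 5.04) and CAGCTG 5.17 times (4.74 to 5.64) as frequent. TGATTG was 4.23 times (4.01 to 4.56) as frequent. The matched medians at these summits were 6.22% for CATCTG, 3.73% for CAGCTG and 8.9% for TGATTG. Flanks alone already held both E-boxes above their matched medians and TGATTG below its own. The folds over matched hexamers therefore do not rank the E-boxes against TGATTG at summits. The leading octamer was CTGATTGC, in 7.26% of distal summits and 0.439% of flanks.

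**Figure D3:**
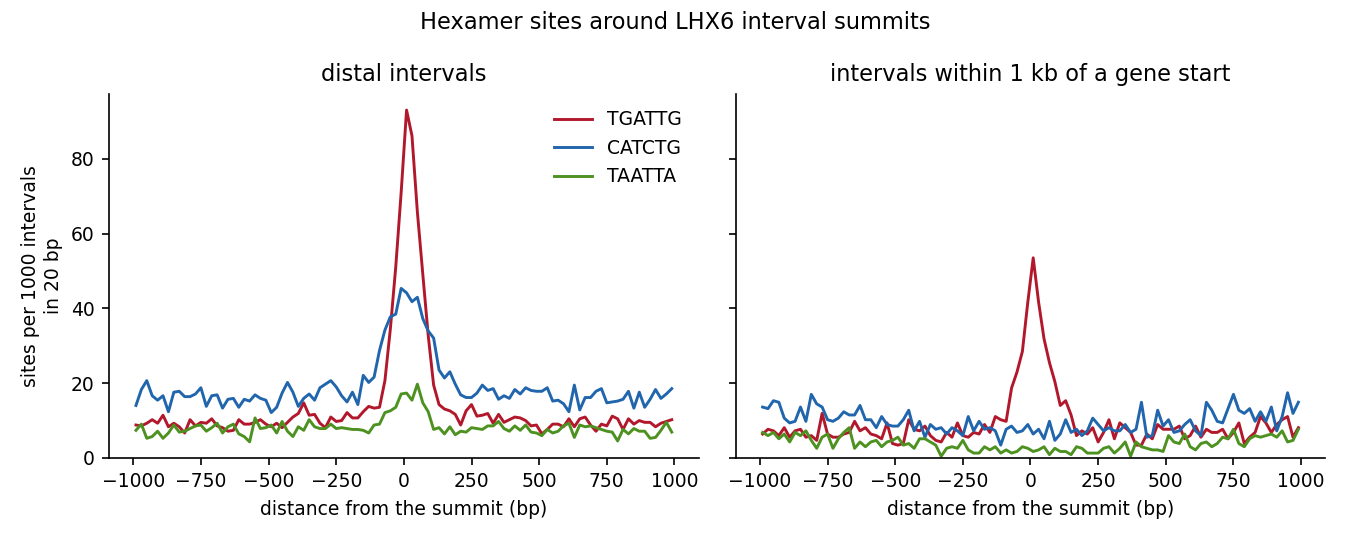
Sites of TGATTG, CATCTG and TAATTA per 1000 intervals in 20 bp steps (y axis) by distance from the interval summit (x axis, bp), for distal intervals and for intervals within 1 kb of a gene start. TGATTG peaks at the summit in both panels, and CATCTG and TAATTA peak in distal intervals alone.

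With distal intervals ranked by height in 10 equal groups, TGATTG was present at 64.0% (59.2 to 68.6) of the summits in the highest group and 22.8% (18.9 to 27.1) in the lowest, and TGATTA at 50% and 19%. CATCTG was at 37.0% (32.4 to 41.8) in the highest group and 22.3% (18.4 to 26.6) in the lowest. TAATTA was at 12.6% (9.55 to 16.1) in the highest group, 16.2% (12.8 to 20.0) in the fourth, where it was most frequent, and 7.60% (5.26 to 10.6) in the lowest.

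**Figure D4:**
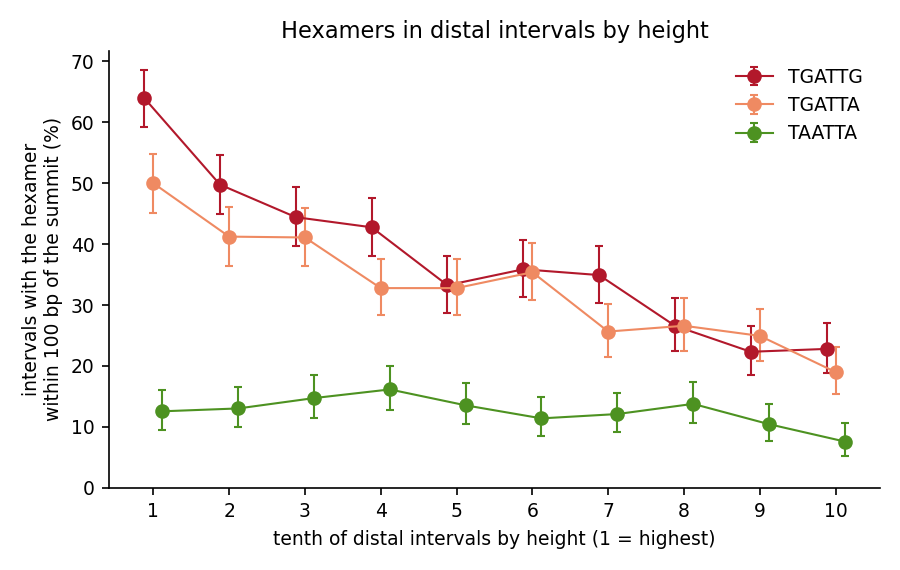
Percent of distal intervals with each hexamer within 100 bp of the summit (y axis) by group of interval height (x axis, 10 equal groups, 1 is the highest), with exact 95% intervals. TGATTG falls from 64.0% to 22.8%.

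At gene starts TGATTG was at 22.6% (20.9 to 24.3) of summits against 7.99% of flanks (exact sign test, p = 2.2e-61), rank 211 of the 2080 hexamers by this test, and CCGCCC ranked 1 (52.3% against 3.74%). Over all intervals TGATTG ranked 5, behind 4 hexamers made of G and C. At gene starts TGATTA was less frequent at summits than in flanks, with 4.84% against 7.60% (exact sign test, p = 7.64e-06), but 2.19 times (1.82 to 2.60) as frequent there as the median of 59 hexamers of the same composition, rank 4. Of the TGATTG sites at gene starts, 70.7% (67.1 to 74.1) were followed by G, which makes the opposite strand a CCAAT box, a common promoter element, against 28.6% (26.7 to 30.5) of those in distal intervals. TGATTG followed by A, C or T was at 7.65% of the summits at gene starts and 5.90% of their flanks, and at 29.1% of distal summits and 6.10% of their flanks.

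LHX6 intervals lay closer together than random positions. The median distance between neighbouring summits was 151 kb, against 252 kb (range 241 to 264) for 1000 random placements (two-sided permutation rank test, p = 0.002, the smallest they can give), and 9.18% of the distances were under 10 kb against 2.70%. The placements were not matched on position relative to genes. With 38.9% of summits within 1 kb of a protein-coding start against 2.36% of random positions, they cannot separate clustering from concentration at gene starts. The genes with most intervals were Dnm3 with 14, Auts2 with 13, Bcas3 with 13, Gpc6 with 11 and Dlx1as, the antisense transcript of Dlx1, with 9. The highest interval of each was intronic in Gpc6 (height 72), Dnm3 (63), Bcas3 (59) and Auts2 (41), and lay within 1 kb of a protein-coding start for Dlx1as (30). Those of Gpc6, Auts2 and Dnm3 lay 452, 397 and 224 kb from the gene start, so these are long genes. The counts per gene were not adjusted for gene length.

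The X chromosome had few LHX6 intervals, 59 in all, or 0.364 per Mb against 2.72 per Mb on the autosomes. The ratio was 0.134, with an exact Poisson 95% interval of 0.102 to 0.173. It was 0.139 (0.0873 to 0.211) at gene starts and 0.13 (0.0891 to 0.184) for distal intervals without a CpG island. Among the autosomes the density ran from 2.06 per Mb on chromosome 14 to 3.86 per Mb on chromosome 11.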

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

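Summits as centre, intervals split by distance to gene starts, single flanks, GENCODE assignments, matching on CpG content, removal of input intervals and every alternative for TGATTG and the X chromosome were chosen after the data were seen. No paired analysis was possible because each group has 1 library, and with unknown depth the number of intervals has no error. The filter on the highest 5% of input values was not run for the number and strength of intervals, since 6 intervals have an input value.

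The number of intervals was 3283 in the higher part by height and 657 in the top 10%, by construction. The share at gene starts was 32.7% and 15.2% in these sets, 31.4% within 500 bp, 43.9% within 5 kb and 38.9% with GENCODE starts. The lower strength at gene starts turned to higher by 0.379 with mean density; the cause was not tested. The number of lists above other genes, 10, was 6 with matching on length, 7 against protein-coding genes, 3 against protein-coding genes matched on length and CpG content, and 7 to 9 under the other alternatives. Facial mesenchyme factors and cleft palate genes passed under each of the 7 alternatives, and 6 lists passed under none. With mean density 2 lists stood apart in strength, facial mesenchyme factors lower (9.71 against 10.4) and housekeeping genes higher (12.5 against 10.4, permutation test, adjusted p = 0.0236 for both). TAATTA had a ratio of centre to flanks of 1.06 with 500 bp windows, whose cause was not tested, and 0.257 at gene starts. Base composition may account for the latter, since TAATTA was not below hexamers of the same composition there (1.33 times, 0.912 to 1.77). Of the 42 alternatives for the main results, 29 kept direction and side of the threshold, stayed within the 95% interval of a share or ratio, or kept a count within 1.5 times its main value, among them both single flanks for TAATTA (1.26 and 1.31), all for TGATTG (4.28 to 6.04) and all for the X chromosome (0.104 to 0.139).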

Other observations

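The hexamer spacings were tested after the hexamers had been seen, the count of the joined sequence was chosen after the spacing result was seen, and the test of 1 active X chromosome was chosen after the X ratio was seen. For 4 homeodomain hexamers and the E-box CATCTG, 1 distance was more frequent than the others in distal intervals. TAATTA was followed after 4 bp by CAGATG, which is CATCTG on the other strand, in 11 distal intervals against a mean of 1.21 over 80 spacings (exact Poisson test, adjusted p = 5.52e-06). The same orientation and gap led for TAATTG (10 intervals, exact Poisson test, adjusted p = 7.64e-05), TGATTA (10 intervals, adjusted p = 0.00338) and TGATTG (9 intervals, adjusted p = 0.0371), and it was the 1 spacing to pass for each. Adjustment here was within each pair. Over all 760 spacings the adjusted p (exact Poisson test) was 5.24e-05 for TAATTA, 0.000181 for TAATTG, 0.00536 for TGATTA and 0.0252 for TGATTG. Of the other 2 pairs tested, TGATTG with CAGCTG had 0 passing spacings (gap of 4 bp in 8 intervals, exact Poisson test, adjusted p = 0.175). TGATTG with TGATTG had 10 passing of 120 within the pair, so the test also called many distances where no single gap stood out. For the joined sequence, the gap and orientation were chosen from these same distal intervals. Each of the 4 homeodomain hexamers and CATCTG was also more frequent at summits than in flanks. Flanks are therefore no test of the gap. The mean over spacings was 1.21 intervals for TAATTA, 1.175 for TAATTG, 1.82 for TGATTA and 1.99 for TGATTG. These 4 hexamers joined to CAGATG by 4 bp occurred in 40 of 4212 distal intervals (0.95%, 0.679 to 1.29), in 1 left flank and in 1 right flank. The highest such interval lay 227 kb from Sox9, the regulator of cartilage formation (chromosome 11, 112875228 to 112876465, height 63), with the sequence TAATTGACAGCAGATG. Others lay in Rora (height 59), Plxdc2 (height 44) and 54.3 kb from Ptgfr (height 43), genes named after their values were seen. A candidate explanation is that LHX6, or another homeodomain factor, binds next to a basic helix-loop-helix factor at this gap; no second factor was measured, and the pair accounts for few of the distal intervals.

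Intervals at gene starts held TGATTG less often than distal intervals, 22.6% against 37.7%. Base composition may account for part of this, since TGATTG was 6.03 times (5.48 to 6.64) as frequent as hexamers of the same composition at gene starts and 4.23 times in distal intervals. CCAAT boxes may inflate the former, with 70.7% of its sites at gene starts followed by G against 28.6% in distal intervals. Without them the values were 2.9 (2.5 to 3.39) and 4.38 (4.09 to 4.66). TGATTG outside CCAAT boxes was thus still lower at gene starts after matching on composition. That CpG-rich gene starts hold the hexamer alike with and without an interval is argued against by TGATTG followed by A, C or T, which was 1.98 times (1.72 to 2.28) as frequent at gene starts with an interval as at those without at the same CpG content. Both 6.03 and 2.9 (2.5 to 3.39) lay above the limit set beforehand for excluding an enrichment of gene starts without regard to sequence, yet it cannot be told apart from binding, since the CCAAT form was 2.24 times (2.04 to 2.48) as frequent at gene starts with an interval, so active gene starts could raise both; leaving out CCAAT boxes and this reading were chosen after the values were seen. No biological explanation was tested, since the design has no sample without LHX6.

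The X chromosome had 0.134 times the intervals per Mb of the autosomes. A copy number of 0.75 in embryos of mixed sex would leave a share of at least 0.543 of autosomal intervals at height limits from 12 to 18, above the upper limit of 0.173, so it does not account for the deficit on its own. Fewer CpG-rich gene starts are argued against by the ratio of 0.13 (0.0891 to 0.184) among distal intervals without a CpG island. With 1 active copy, shares from 0.16 to 0.429 would be left. The ratio lies below all 7, and its upper limit of 0.173 reaches only that at a height limit of 18, the others being 0.178 or more. The lowest LHX6 height in the list was 10 and the lower quartile 18, so a limit of 18 lies above part of the listed intervals. Limits under 12 were not tried. The explanation of 1 active copy stays undecided by the overlap at 1 of the 7 limits. The sex of the embryos and the mappability of the X chromosome were not tested.

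Facial mesenchyme transcription factors had an interval in 79.7% of cases. Gene length and CpG content are argued against as the whole cause, since matched protein-coding genes had one in 20.3% to 43.8% of cases in the central 95% of draws. Enrichment at open chromatin that does not depend on the sequence bound may contribute: their distal intervals held TGATTG in 20.2% against 38.1% of other distal intervals, a ratio of 0.531 (0.355 to 0.795). Without intervals at CpG islands the ratio was 0.681 (0.459 to 1.01), whose interval includes 1. No data on open chromatin were analysed here, so binding by LHX6 and general enrichment at active genes stay open.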
